A study of Mus musculus with 12 samples.

How the data were processed

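Gene expression was measured in pituitaries of mice with an intact or a knocked-out Crhr1 gene, which encodes the receptor for corticotropin-releasing hormone. Per the labels, every mouse received metyrapone, an inhibitor of the steroid beta-hydroxylase that makes corticosterone, at 150 mg/kg 12 h before and 100 mg/kg directly before stress. Stressed mice were restrained for 30 min and killed 1 h or 3 h after the start of stress according to the sample labels, while the design text counts from the stress without naming its start, and control mice formed the remaining treatment. Pituitary RNA was pooled, amplified once, coupled with Cy3 and hybridised to Illumina mouse bead arrays, per the labels. The 6 groups, 3 treatments in each of 2 genotypes, had 2 arrays each, 12 in all, which the titles call technical replicates. They were taken as 2 arrays of 1 pool, although the design text's N = 2 per group could also count pools. The number of mice per pool is not given in the sources used here. The source field of the knockout 3 h and knockout control arrays names death at 1 h after restraint, against their titles, and the titles were used. All arrays named replicate 1 lay on 1 slide and all named replicate 2 on the other, in the same group order, so the slide and the replicate number are the same factor, and array position cannot be told apart from the group.

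The deposited file of each array holds the raw mean bead intensity of 46147 probes, neither background-subtracted nor normalized, per the file headers and the submitters' processing notes, which name BeadStudio without a version. The same deposited files give a detection p-value per probe, made by the authors with that software against negative control beads. A separate table of the authors holds a second set of intensity values for 46133 of these probes, on a linear scale and already background-subtracted and normalized between arrays, as tested on the values. That table had been scaled in 2 parts of the array, split at probe ID 100000000. Array medians in it lay between 9.70 and 9.71, the method is not stated, and it served only as an alternative. The 14 probes absent from it were left out of tests.

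Computation started from the raw intensities. They were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with the background taken from the detection p-values and an offset of 16, then quantile normalized between arrays and put on the log2 scale. Probes were kept when the detection p-value was under 0.01 on at least 2 of the 12 arrays, which left 14405. Gene names came from the probe table given for the array, where 29542 probes had 1 gene symbol, 11 had several and 16580 had none. The RefSeq gene table of GRCm38.p6 served to check symbols and to find which genes neighbour each other. No coordinates are given, since the sources used here do not name the assembly the array was designed on. For each gene symbol the probe with the highest mean was used, and probes without a symbol stayed in as unnamed features, which gave 11766 features, 8592 of them named.

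Precision is limited by the number of arrays. Between 6119 and 13506 probes were detected per array, and the correlation between the 2 arrays of a group, across probes, lay between 0.926 and 0.981. Intensities above 60000 occurred for 1 to 3 probes per array, so no order or level is read from the brightest hormone genes. Where a gene was not detected on any array of the dimmer group, the difference has only a bound. It is given as at least N-fold, from the mean of the brighter group's arrays against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

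Comparisons were fitted with lmFit and eBayes of limma on all 12 arrays with 1 term per group. They were stressed against control within each genotype at 1 h and 3 h, knockout against wild type in controls, and the difference between the genotypes' stress responses at each time (interaction). In 3 further comparisons the 2 arrays of a pool were averaged first and the 6 pools were fitted with genotype and treatment as terms. Knockout against wild type at 1 h and at 3 h was added after the data were seen. A feature passed the threshold at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1.5-fold. Errors of differences are limma standard errors, and errors of levels are standard deviations. Of 26 gene lists written down for pathways, pituitary cell types and other cell types, the 21 with at least 5 measured genes were tested with camera of limma, with a preset correlation between genes of 0.01 and again with an estimated one. Adjusted p-values of lists are over the 21 lists of a comparison. Some lists share members, so their calls are not independent. Dusp1 is in the cAMP/CREB, MAPK feedback and glucocorticoid lists, and Fos and Nr4a2 are in the immediate early and cAMP/CREB lists. Lcn2 is in the glucocorticoid and the folliculostellate and stem cell lists. The list named immediate early transcription factors also holds Arc and Ier3, which are not transcription factors, and its counts include them where measured.

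Groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule, the genes named for the wild-type responses, the interactions and the genotype comparison of pools are the 10 largest differences in each direction among features past the threshold whose group values did not overlap and that were detected on every array of the higher group. For interactions only the threshold applied, and for the genotype comparison of pools the direction had to be the same in all 3 treatments. Other comparisons name the 3 largest in each direction. Each list described may name up to 4 members with the largest absolute difference, and Crhr1, Pomc, Gh, Prl, Tshb, Fshb, Lhb, Cga, Fos and Nr4a1 were followed throughout. Nr4a1 did not pass the detection filter. Unnamed probes were passed over, and list members outside this rule are given only where the text says that they were chosen afterwards.

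Quantile normalization, the fits and camera were tested on simulated log2 values made from these arrays, with 100 features changed per fold size among 11766. Noise was drawn independently for each gene and with the same spread on every array. Background correction, the detection filter and an array with few detected probes were not part of the simulation. For the wild-type 1 h comparison, 31% of changes of 1 on the log2 scale and 88% of changes of 2 were recovered, with 9 false calls. For the 1 h interaction the shares were 5% and 56% with 7 false calls, and for the genotype comparison of pools 33% and 96% with 5 false calls. A simulated shifted list gave a camera p of 8.02e-38 and an unshifted one 0.117. Since the simulated genes varied independently, this does not test camera where genes are correlated.

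The alternatives were median centring, no background correction, the authors' table, no detection filter, detection on all arrays, every probe counted, eBayes with trend and robust, the replicate number as a block, fitting only the groups compared, array quality weights, no or a 2-fold threshold, and leaving out each array or pool in turn. Normalizing the 2 array parts apart was added after the data were seen. The slide as a block was not run separately, since it is the replicate block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.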

Results

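Pituitary RNA of wild-type and Crhr1 knockout mice was profiled on bead arrays in 3 treatments per genotype: control, 1 h and 3 h after the start of a 30 min restraint. Each of the 6 groups was taken as 1 RNA pool on 2 arrays, 12 arrays in all, since the titles call the arrays technical replicates. The design text gives N = 2 per group, which could also count 2 pools. On the reading used, errors and p-values of the array comparisons measure the spread between technical arrays of pools, not between mice. In the 3 comparisons of pools they measure how far pool means depart from additive effects of genotype and treatment. That departure holds variation between pools and any real interaction. Of 46147 probes per array, between 9212 and 13506 were detected at p under 0.01 on 11 arrays. The exception was replicate 2 of the knockout 3 h pool, where 6119 probes (13.3%) were detected and the correlation with its replicate was 0.926, against 0.967 to 0.981 in the other groups, across probes. Log2 differences between the 2 arrays of this pool had an SD of 0.698, against 0.327 to 0.428 in the other groups. The array fits use 1 spread for all groups, so errors and p-values of comparisons with this pool tend to be too small. In all 6 groups replicate 2, on its own slide, had fewer detected probes and a higher median raw intensity than replicate 1, and the slide is a term of a fit only where stated. According to the design text, metyrapone was given to block the negative feedback of corticosterone, so that restraint would activate signalling through the receptor.

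The targeted gene was measured by 3 probes. Probe 5390647 was detected on 4 of 6 wild-type arrays and on 0 of 6 knockout arrays, at log2 intensities of 6.19 ± 0.18 in wild type and 5.28 ± 0.17 in knockout (SD, n = 3 pools each). The knockout level is below detection, so no size of the difference is given, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 pools allow. Probe 450161 was detected on 1 of 6 arrays of each genotype and did not differ past the test (-0.00, exact permutation p = 1, n = 3). Probe 3140070 was detected on no array of either genotype. Per array, probe 5390647 lay between 5.77 and 6.78 in wild type and between 4.72 and 5.75 in knockout. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so they check the genotype labels little.

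Stress in wild-type pituitaries was examined first at 1 h. Npas4, a transcription factor switched on by electrical activity, rose by 1.66 ± 0.21 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 0.0311). Plagl1, an imprinted zinc finger transcription factor, was at least 4.17-fold higher (adjusted p = 0.0129), and Cyp20a1, a cytochrome P450, rose by 1.86 ± 0.20, while a second Cyp20a1 probe differed by 1.24 and did not pass. Spink8, a serine peptidase inhibitor, was at least 5.25-fold lower (adjusted p = 7.66e-04), and Ttc27, a tetratricopeptide repeat protein, fell by 2.75 ± 0.21 (adjusted p = 0.00163).

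Lists of activation genes were compared in wild type at 1 h. Of 20 measured genes in the list named immediate early transcription factors, which also holds Arc and Ier3, 19 had positive differences with a median of 0.84. The count higher was 9 adjusted over the list alone and 1, Npas4, over all genes. The list's camera adjusted p = 1.89e-14, and adjusted p = 0.0839 with an estimated correlation. Fos, the AP-1 subunit used as a mark of recent activity, differed by 2.03 ± 0.40 (adjusted p = 0.244) and Jun by 1.46 ± 0.33. Among 15 MAPK phosphatases and feedback genes, 3 were higher adjusted over the list alone, with differences of 1.00 ± 0.20 for Dusp5 and 0.90 ± 0.20 for Dusp1 (camera adjusted p = 1.74e-04, and adjusted p = 0.122 with an estimated correlation). Of 15 cAMP/CREB-responsive genes, 2 were higher adjusted over the list alone, and Nr4a2, a nuclear receptor, differed by 1.08 ± 0.34 (camera adjusted p = 0.00157, and adjusted p = 0.0839 with an estimated correlation). Of 25 glucocorticoid-responsive genes, 22 had positive differences, 2 were higher adjusted over the list alone, and the median was 0.25. Rasd1, a small G protein, differed by 1.38 ± 0.41 (camera adjusted p = 4.52e-05, and adjusted p = 0.0839 with an estimated correlation).

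Among markers of other cells in the same comparison, all 5 folliculostellate and stem cell markers had positive differences and 1 was higher adjusted over the list alone, with 0.73 ± 0.16 for Lcn2 (camera adjusted p = 3.14e-04, and adjusted p = 0.0839 with an estimated correlation). Of 5 red blood cell markers, 2 were lower adjusted over the list alone, with -0.86 ± 0.17 for the globin gene Hba-a1 (camera adjusted p = 0.00617, and adjusted p = 0.0839 with an estimated correlation). The 19 ribosomal protein genes had a median of -0.15, and none was called over the list alone (camera adjusted p = 0.00509, and adjusted p = 0.169 with an estimated correlation). Over all 11766 features, 8 passed the threshold in limma, 5 higher and 3 lower, and 661 had an unadjusted p under 0.05 where chance gives 588. The count was 4 without wild-type 1 h replicate 1, 3 without wild-type 1 h replicate 2 and 3 without wild-type control replicate 2, and Spink8 and Ttc27 passed under each omission. Npas4 did not pass with the slide as a block.

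At 3 h in wild type, Nr4a2 fell by 2.26 ± 0.34 (SE, n = 2 arrays per group, adjusted p = 0.0435), and the AP-1 gene Fosl2 fell by 1.70 ± 0.24 (adjusted p = 0.0341). Npas4 fell to below detection on both arrays (adjusted p = 0.0387), and Crem, a cAMP-responsive transcription factor, fell by 1.15 ± 0.16. Socs3, a feedback inhibitor of cytokine signalling, rose by 1.99 ± 0.16 (adjusted p = 0.00193), Serpina3n, a protease inhibitor, by 2.45 ± 0.29, and Lcn2, a siderophore-binding protein, by 1.20 ± 0.16. Hif3a, a hypoxia-related transcription factor, rose by 1.47 ± 0.16 (adjusted p = 0.0163), while a second Hif3a probe differed by -0.27 and did not pass.

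The other wild-type genes named at 3 h had mixed functions. Eprs, a transfer RNA synthetase, was at least 3.50-fold higher and the Fc receptor chain Fcer1g at least 1.62-fold higher, and the globin gene Hbb-b2 rose by 1.82 ± 0.25, while the globin gene Hbb-bt, undetected at 3 h, lay at least 2.37-fold lower and did not pass (adjusted p = 0.221). Spink8 was at least 5.62-fold lower (adjusted p = 2.67e-04), Txnl1, a thioredoxin-like protein, at least 3.89-fold lower and Csrp1, a LIM domain protein, at least 3.80-fold lower. Enc1, an actin-binding protein, fell by 1.56 ± 0.17, the kinase gene Stk4 by 1.59 ± 0.22, the receptor gene Gpr83 by 1.33 ± 0.19 and the Ras activator Rasgrp1 by 1.33 ± 0.16. Second probes of Gpr83 and Rasgrp1 differed by -0.21 and -0.11 and did not pass.

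Of the 20 immediate early transcription factors, 3 fell at 3 h over all genes and 7 adjusted over the list alone, with a median of -0.38. The list's camera adjusted p = 9.93e-04, and adjusted p = 0.313 with an estimated correlation. Egr1 differed by -1.56 ± 0.24 (adjusted p = 0.0532). Of 15 cAMP/CREB-responsive genes, 2 fell over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.133 with an estimated correlation). Among 25 glucocorticoid-responsive genes, 2 rose over all genes, Hif3a and Lcn2, and adjusted over the list alone 9 were higher and 2 lower, with a median of 0.48. This list had camera adjusted p = 4.05e-05, and adjusted p = 0.133 with an estimated correlation. The metallothionein gene Mt2 differed by 1.98 ± 0.31 (adjusted p = 0.0536) and Pdk4, a brake on pyruvate oxidation, by 1.52 ± 0.31. Of 13 cholesterol genes, 3 were higher adjusted over the list alone, with 0.75 ± 0.14 for Msmo1 (camera adjusted p = 0.00322, and adjusted p = 0.313 with an estimated correlation). Of 5 folliculostellate and stem cell markers, 1 rose over all genes and 3 were higher adjusted over the list alone (camera adjusted p = 9.93e-04, and adjusted p = 0.146 with an estimated correlation). The 1 that rose over all genes was Lcn2, already counted among the glucocorticoid-responsive genes. Of 11 heat shock genes, 2 fell over all genes, Hsph1 by 1.18 ± 0.17 and Dnajb1 by 0.97 ± 0.14. Over all features, 27 passed the threshold in limma, 10 higher and 17 lower. Leaving out any 1 of the 12 arrays moved this count by over 1.5 times, from 2 without wild-type 3 h replicate 1 to 90 without knockout 3 h replicate 1, and Spink8 and Txnl1 passed under each omission. Fosl2, Npas4 and Fcer1g did not pass with the slide as a block.

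In knockout pituitaries at 1 h, Fos rose by 5.54 ± 0.40 on the log2 scale (SE, n = 2 arrays per group, adjusted p = 8.61e-04), from a level of 6.42 ± 0.31 in controls to 11.96 ± 0.30. Dusp1, a MAPK phosphatase, rose by 2.60 ± 0.20 (adjusted p = 0.00107). Arc, a synaptic immediate early gene, was at least 6.35-fold higher, Npas4 at least 3.18-fold (adjusted p = 0.00140) and Csrnp1 at least 2.48-fold. Emb, a membrane glycoprotein that carries monocarboxylate transporters to the cell surface, was at least 9.61-fold higher than in knockout controls, and Cyp26b1, which breaks down retinoic acid, at least 9.21-fold. Eme1, a subunit of a DNA repair nuclease, was at least 2.12-fold lower.

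Of 20 immediate early transcription factors, 6 rose in knockout at 1 h over all genes and 13 were higher adjusted over the list alone, with a median of 0.80 and 19 positive differences. The list's camera adjusted p = 3.83e-17, and adjusted p = 0.0523 with an estimated correlation. Of 15 cAMP/CREB-responsive genes, Fos and Dusp1 rose over all genes and 3 were higher adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.130 with an estimated correlation). Of 15 MAPK phosphatases and feedback genes, 1 rose over all genes, and adjusted over the list alone 4 were higher and 1 lower, with 1.43 ± 0.35 for Dusp8 and -0.71 ± 0.21 for Rgs4 (camera adjusted p = 0.00242, and adjusted p = 0.188 with an estimated correlation). Of 25 glucocorticoid-responsive genes, 1 rose over all genes, Dusp1, and 6 were higher adjusted over the list alone, with 1.71 ± 0.41 for Rasd1 (camera adjusted p = 3.19e-06, and adjusted p = 0.0643 with an estimated correlation). Of 13 circadian clock genes, 0 passed over all genes, and adjusted over the list alone 6 were higher and 1 lower. Bhlhe40, a clock repressor, differed by 1.15 ± 0.20 and Nr1d1 by 1.01 ± 0.22 (camera adjusted p = 3.13e-04, and adjusted p = 0.0523 with an estimated correlation). Of 5 red blood cell markers, 2 were lower adjusted over the list alone, with -0.68 ± 0.15 for Hbb-bs (camera adjusted p = 0.0209, and adjusted p = 0.130 with an estimated correlation). The 6 neuron and oligodendrocyte markers all had negative differences and none was called over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.188 with an estimated correlation). Over all features, 27 passed the threshold in limma, 24 higher and 3 lower. Leaving out any 1 of the 12 arrays moved this count by over 1.5 times, from 6 without knockout 1 h replicate 2 to 77 without knockout 3 h replicate 1, and Fos, Emb, Cyp26b1, Npas4 and Dusp1 passed under each omission. Csrnp1 and Eme1 did not pass with the slide as a block, and the neuron and oligodendrocyte list was not called.

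**Figure D1:**
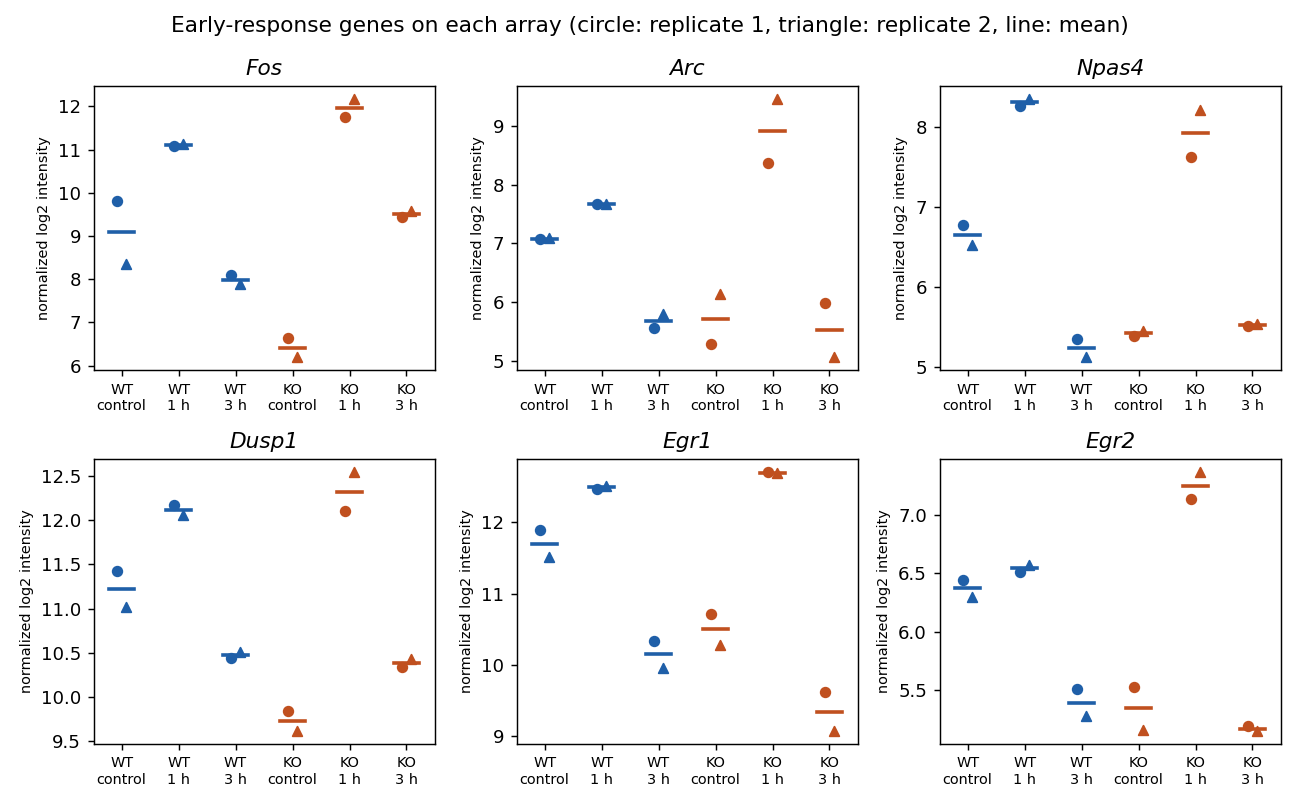
Normalized log2 intensities (vertical axis) of Fos, Arc, Npas4, Dusp1, Egr1 and Egr2 on each of the 12 arrays, by genotype and treatment, with points for arrays and lines for group means. Fos lay at 9.08 in wild-type and 6.42 in knockout controls, and at 11.12 and 11.96 at 1 h.

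At 3 h in knockout, Fos still lay 3.10 ± 0.40 above controls (SE, n = 2 arrays per group, adjusted p = 0.00647), while the early growth response gene Egr3 was at least 2.19-fold lower (adjusted p = 0.00234) and Nr4a2 fell by 1.64 ± 0.34. Emb was at least 7.45-fold higher (adjusted p = 2.54e-05), Lipf, a gastric lipase, at least 13.9-fold (adjusted p = 9.90e-05) and Lyz1, a lysozyme, at least 4.33-fold. Txnl1 was at least 1.95-fold lower and Frmd7, a FERM domain protein, at least 2.48-fold lower. Socs3 rose by 1.66 ± 0.16 (adjusted p = 0.00235). Tshb, the thyrotropin subunit, fell by 1.14 ± 0.18 (adjusted p = 0.0109), the only 1 of the followed hormone genes to pass in any comparison. Errors in this comparison come from the spread shared by all groups, although the 2 arrays of this pool differed more than those of any other. Pomc, Gh and Prl lay near the upper end of the scanner's range, so their not passing says little. Quantile normalization also gives the brightest probes the same values by rank, and Gh and Prl differed by 0 between the genotypes at 3 h.

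No list was called by camera in knockout at 3 h, and members went both ways. Of 20 immediate early transcription factors, 2 rose and 5 fell. Of 15 cAMP/CREB-responsive genes, 3 rose and 4 fell, with -1.04 ± 0.16 for Crem. Of 25 glucocorticoid-responsive genes, 3 rose and 1 fell, with 1.05 ± 0.16 for the crosslinking enzyme Tgm2, 0.85 ± 0.16 for Lcn2 and -1.52 ± 0.22 for Errfi1, an inhibitor of growth factor receptors. Of the unfolded protein response genes, the transcription factor Atf4 rose by 1.94 ± 0.33. Nr1d2, a clock repressor, fell by 1.90 ± 0.29, while a second Nr1d2 probe differed by 0.73 (adjusted p = 0.333), and Plvap, an endothelial marker, rose by 1.25 ± 0.19. Over all 11766 features, 1243 passed the threshold in limma, 472 higher and 771 lower, and the median of all features was -0.11, or 0.05 with median centring. The count was far lower with array quality weights, and lower still when only the arrays of the groups compared were fitted. Of the 2 arrays of this pool, replicate 2 was the array with few detected probes. Without it 526 features passed, 445 of them among the 1243. Of the lower calls 83.5% were detected on replicate 1 and 40.6% on replicate 2, and of the higher calls 99.8% and 83.7%. The count was 3266 without replicate 1 of the same pool, 51 and 26 without knockout control replicates 1 and 2, and 740 and 758 without wild-type 1 h replicates 1 and 2. Emb, Lipf, Lyz1, Egr3, Txnl1 and Socs3 passed under each omission.

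Whether the genotypes answered alike was examined over all 11766 features, with wild-type and knockout responses measured on separate arrays. Across genes, which are not independent replicates, the responses at 1 h had a Pearson correlation of -0.02 and a Spearman correlation of -0.06, and those at 3 h 0.17 and 0.17. Between its own 2 slides the wild-type response correlated at 0.39 at 1 h and 0.30 at 3 h, and the knockout response at 0.50 at both times. These slide values rest on 1 array per group and the correlations between genotypes on means of 2, so noise between arrays alone need not account for the lower values. With 1 pool per group, variation between pools stays open, so a low correlation between genotypes does not by itself show unlike responses. Immediate early transcription factors had medians of 0.84 in wild type and 0.80 in knockout at 1 h. At 1 h Npas4 was higher in both genotypes, the only feature past the threshold in both, where independent lists would share 0.0102. At 3 h, 4 features were higher in both and 7 lower, where independent lists would share 0.401 and 1.11. Both genotypes' tests use the same spread of each feature, which by itself favours calls in both. The numbers for independent lists are therefore too low a mark, at 1 h as well. The shared genes at 3 h were Socs3, Lcn2 and Eprs among those higher and Nr4a2, Fosl2, Crem, Hsph1, Txnl1, Spink8 and Fam13c, with 1 unnamed feature besides. Of the 8 wild-type calls at 1 h, 6 had the same sign in knockout, and of the 27 at 3 h, 19 did.

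The test of the difference between responses at 1 h called 6 features, 5 more positive in knockout and 1 more negative. They were Emb, with a difference of 4.76 ± 0.26 (SE, n = 2 arrays per group, adjusted p = 1.99e-04), Cyp26b1 with 3.48 ± 0.27 (adjusted p = 0.00260), Spink8 with 2.69 ± 0.29 (adjusted p = 0.0175), Ttc27 with 2.52 ± 0.30 (adjusted p = 0.0320) and 2 unnamed probes. Emb lay at 10.75 and 10.61 in wild-type control and 1 h pools, at 4.90 and undetected in knockout controls, and at 9.51 in knockout at 1 h, so the fitted differences of Emb and Cyp26b1 rest on a group below detection. That of Spink8 rests on wild type at 1 h, undetected as well. Fos had a difference of 3.51 ± 0.57 that did not pass (adjusted p = 0.0968). Of 20 immediate early transcription factors, 6 responded more in knockout adjusted over the list alone and 0 over all genes, with 1.74 ± 0.25 for Egr2, undetected in knockout controls (camera adjusted p = 0.0135, and adjusted p = 0.424 with an estimated correlation). This list lay lower in knockout than in wild-type controls (median -0.28) and was not called between the genotypes at 1 h. A larger response therefore cannot be told apart from a lower level in the knockout control pool. Leaving out 1 of 9 arrays moved the count of 6 by over 1.5 times, from 2 without wild-type 1 h replicate 2 to 12 without knockout 1 h replicate 1, and Emb and Cyp26b1 passed under each omission. Ttc27 did not pass with the slide as a block.

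At 3 h the responses differed for 20 features, 14 more positive and 6 more negative in knockout, a lean that was absent without background correction. Mt3, a metallothionein of the nervous system, differed by 3.37 ± 0.24 (SE, n = 2 arrays per group, adjusted p = 7.74e-04), Fos by 4.18 ± 0.57 (adjusted p = 0.0368), Emb by 4.21 ± 0.26, Csrp1 by 4.27 ± 0.56 and Cyp26b1 by 1.85 ± 0.27. Lipf differed by 4.22 ± 0.31 (adjusted p = 7.74e-04), Dmbt1, a mucosal glycoprotein, by 3.88 ± 0.26 (adjusted p = 6.78e-04) and Lyz1 by 3.48 ± 0.33 (adjusted p = 0.00501). Rasgrp1 differed by 2.04 ± 0.23 and Ddit4l by 2.32 ± 0.34, whereas Eme1, the potassium channel gene Kcnk10, 1700109H08Rik and the RNA-binding gene Pcbp4 differed by -2.66 ± 0.38, -2.20 ± 0.32, -2.13 ± 0.30 and -1.81 ± 0.23. A second Rasgrp1 probe differed by 0.17 (adjusted p = 0.836). These are fitted values, and they rest on groups below detection for Lipf and Lyz1 (both controls and wild type at 3 h), Dmbt1 (wild type at 3 h), Csrp1 (wild type at 3 h and knockout controls), Emb and Cyp26b1 (knockout controls), and Eme1 and Kcnk10 (every group compared but knockout controls). No list was called by camera. Adjusted over the list alone, 2 of 25 glucocorticoid-responsive genes responded more and 3 less in knockout, with a median of -0.60, and Hif3a and Mt2 had differences of -1.18 ± 0.23 and -1.75 ± 0.44 that did not pass over all genes. Leaving out 1 of 11 arrays moved the count of 20 by over 1.5 times, from 4 without wild-type 3 h replicate 1 to 1818 without knockout 3 h replicate 1, and Lipf, Emb, Dmbt1 and Mt3 passed under each omission. With the slide as a block the count was 50.

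**Figure D2:**
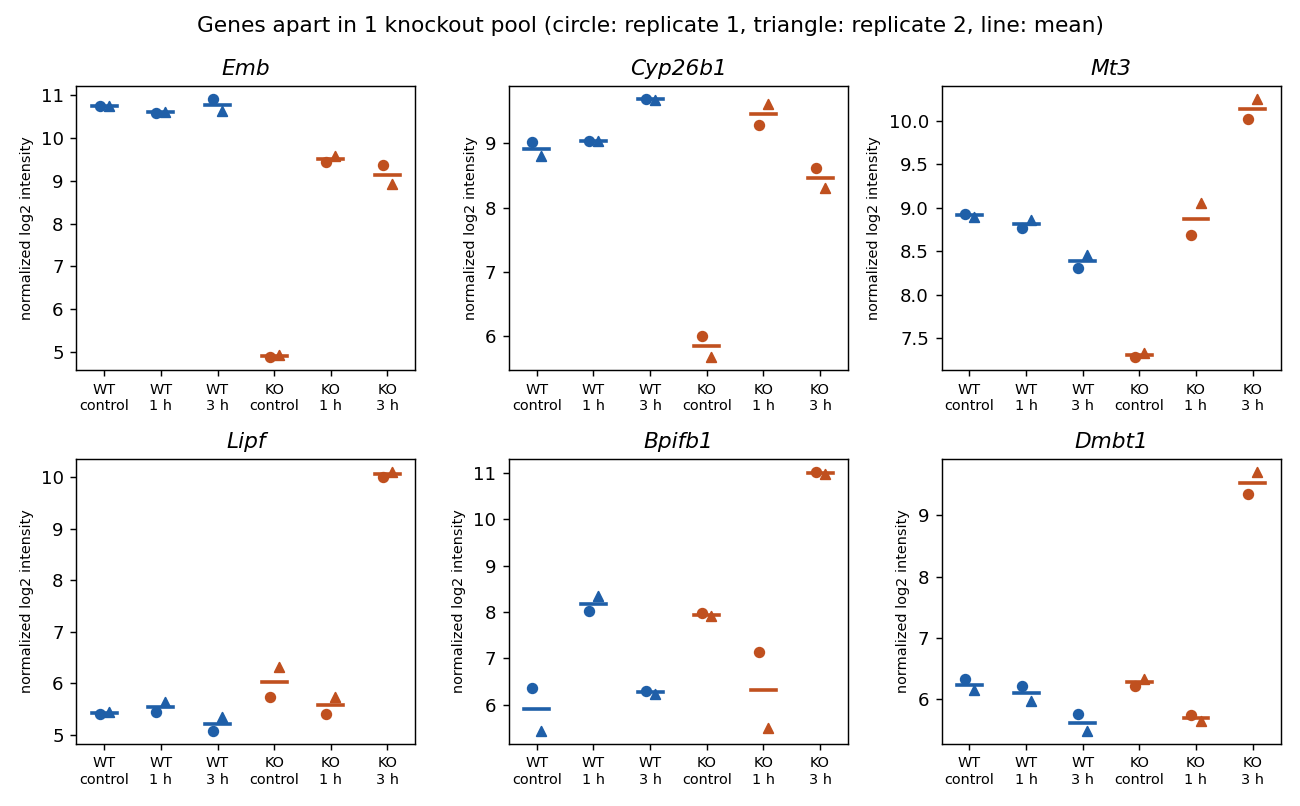
Normalized log2 intensities (vertical axis) of Emb, Cyp26b1, Mt3, Lipf, Bpifb1 and Dmbt1 on each of the 12 arrays, by genotype and treatment, with points for arrays and lines for group means. Emb lay at 4.90 in knockout controls and between 9.14 and 10.78 in the other groups, and Lipf at 10.05 in knockout at 3 h and between 5.22 and 6.03 elsewhere.

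In control pools, Emb was at least 22.6-fold lower in knockout than in wild type (SE of the log2 difference 0.18, n = 2 arrays per group, adjusted p = 1.46e-06), Cyp26b1 at least 6.32-fold lower and Csrp1 at least 3.34-fold lower. Fos was lower by -2.67 ± 0.40 on the log2 scale (adjusted p = 0.0187) and Dusp1 by -1.50 ± 0.20 (adjusted p = 0.0147). Cartpt, a neuropeptide precursor of the posterior lobe list, was at least 2.11-fold lower, and Gal, which encodes galanin, and Ghrhr, the receptor for growth hormone-releasing hormone, differed by -1.28 ± 0.16 and -1.23 ± 0.21, while a second Ghrhr probe differed by -0.86 and did not pass. Frmd7 was at least 3.80-fold higher, Acat3, a thiolase, at least 3.23-fold and the kinase gene Ulk4 at least 2.74-fold, and the stem cell marker Sox9 was higher by 1.54 ± 0.24.

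Of 20 immediate early transcription factors, 5 were lower in knockout controls over all genes, among them Fos and Egr1 (-1.20 ± 0.24), and adjusted over the list alone 6 were lower and 2 higher (camera adjusted p = 0.0149, and adjusted p = 0.277 with an estimated correlation). Of 15 cAMP/CREB-responsive genes, 2 were lower over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.115 with an estimated correlation). Of 25 glucocorticoid-responsive genes, 4 were lower over all genes, and adjusted over the list alone 6 were lower and 1 higher, with -1.31 ± 0.16 for Tgm2, while the cell cycle inhibitor Cdkn1a was at least 1.79-fold lower (camera adjusted p = 0.00385, and adjusted p = 0.115 with an estimated correlation). Of 6 lactotrope markers, Gal was lower over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 0.0250, and adjusted p = 0.133 with an estimated correlation). Of 5 red blood cell markers, 2 were higher over all genes, Hbb-b2 by 1.78 ± 0.25 and Hbb-bs by 0.80 ± 0.15 (camera adjusted p = 0.0105, and adjusted p = 0.115 with an estimated correlation). Of 9 leukocyte markers, 1 was higher adjusted over the list alone, with 0.74 ± 0.23 for H2-Ab1 (camera adjusted p = 0.0182, and adjusted p = 0.115 with an estimated correlation). All 7 proliferation genes had positive differences and 3 were higher adjusted over the list alone, with 1.06 ± 0.27 for Mcm6 (camera adjusted p = 0.00499, and adjusted p = 0.115 with an estimated correlation). Of 5 interferon-induced genes 2, and of 19 respiratory chain genes 3, were higher adjusted over the list alone, with 0.60 ± 0.14 for Psmb8 and 0.73 ± 0.16 for Atp5j2 (camera adjusted p = 0.0384 and 0.0250, and adjusted p = 0.266 and 0.115 with an estimated correlation). Over all features, 271 passed the threshold in limma, 98 higher and 173 lower. Leaving out any 1 of the 12 arrays moved this count by over 1.5 times, from 2 without knockout control replicate 1 to 773 without knockout 3 h replicate 1, and Emb and Cyp26b1 passed under each omission. With the slide as a block the count was 444.

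Knockout was also compared with wild type after stress, in comparisons added after seeing the data. At 1 h, Ttc27 was higher by 3.29 ± 0.21 (SE, n = 2 arrays per group, adjusted p = 6.64e-04), the nuclear envelope gene Sun2 by 1.74 ± 0.24 and the RNA-binding gene Cirbp by 1.71 ± 0.24. Plagl1 was at least 3.60-fold lower, Dnah9, an axonemal dynein chain, was 3.99-fold lower (adjusted p = 0.0227), and Ugt8a, which makes galactosylceramide, was at least 1.51-fold lower. Of 11 heat shock genes, 1 was lower over all genes and 2 adjusted over the list alone, with -1.01 ± 0.18 for Hspb1 (camera adjusted p = 0.0312, and adjusted p = 0.258 with an estimated correlation). Of 5 red blood cell markers, 3 were higher adjusted over the list alone, with 1.24 ± 0.25 for Hbb-b2, and 18 of 19 ribosomal protein genes had positive differences (camera adjusted p = 0.00850 for each list, and adjusted p = 0.237 and 0.271 with an estimated correlation). In limma 93 features passed, 20 higher and 73 lower. Leaving out any 1 of the 12 arrays moved this count by over 1.5 times, from 2 without wild-type 1 h replicate 1 to 428 without knockout 3 h replicate 1, and Ttc27 passed under each omission. With the slide as a block the count was 219.

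At 3 h, knockout exceeded wild type in Lipf by at least 15.8-fold (SE of the log2 difference 0.22, n = 2 arrays per group, adjusted p = 2.95e-05), in Dmbt1 by at least 11.1-fold (adjusted p = 2.95e-05) and in Bpifb1, a secreted protein of mucosal epithelia, by 4.73 ± 0.47 on the log2 scale (adjusted p = 0.00327). The genes furthest below wild type were Obsl1, a cytoskeletal adaptor, with -2.94 ± 0.40 and -0.74 and 0.27 at its other probes, Ppp1r3c, a glycogen-targeting phosphatase subunit, with -2.48 ± 0.39, and Ceacam10, at least 2.02-fold lower. Of 25 glucocorticoid-responsive genes, 5 were lower over all genes, and adjusted over the list alone 13 were lower and 1 higher, with a median of -0.87. This list had camera adjusted p = 1.71e-07, and adjusted p = 0.0561 with an estimated correlation. Hif3a differed by -1.88 ± 0.16 (adjusted p = 0.00301), while a second Hif3a probe differed by 0.52 (adjusted p = 0.608), and Cdkn1a was at least 1.66-fold lower. Of 6 lactotrope markers, 3 were lower and 1 higher, with -1.68 ± 0.16 for Gal, -1.07 ± 0.14 for the angiotensin receptor gene Agtr1a and 0.91 ± 0.18 for the dopamine receptor gene Drd2 (camera adjusted p = 0.0480, and adjusted p = 0.239 with an estimated correlation). All 9 leukocyte markers had positive differences, 1 higher over all genes and 3 adjusted over the list alone, and Lyz1 was at least 4.93-fold higher (camera adjusted p = 6.57e-05, and adjusted p = 0.0561 with an estimated correlation). Lyz1 is also a gene of secretory epithelia, like Lipf, Dmbt1 and Bpifb1, and without it, a check added after seeing the data, the 8 other markers had a median of 0.43 (camera adjusted p = 0.00540, and adjusted p = 0.120 with an estimated correlation). Of 7 fibroblast markers, 2 were higher adjusted over the list alone, with 0.79 ± 0.19 for Mgp (camera adjusted p = 0.00940, and adjusted p = 0.156 with an estimated correlation). Of 6 gonadotrope markers, 1 was higher adjusted over the list alone (camera adjusted p = 0.0296, and adjusted p = 0.156 with an estimated correlation). The pericyte marker Rgs5 was higher by 1.52 ± 0.24, but a second Rgs5 probe differed by -3.05, also past the threshold. Of 10 endothelial and pericyte markers no other passed over all genes (camera adjusted p = 0.0480, and adjusted p = 0.366 with an estimated correlation), and of 13 cholesterol genes 1 was lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0316, and adjusted p = 0.371 with an estimated correlation). In limma 203 features passed, 64 higher and 139 lower. Leaving out any 1 of the 12 arrays moved this count by over 1.5 times, from 12 without wild-type 3 h replicate 1 to 2597 without knockout 3 h replicate 1, and Lipf, Bpifb1, Dmbt1, Lyz1, Cdkn1a, Hif3a and Gal passed under each omission. With the slide as a block the lactotrope, cholesterol, and endothelial and pericyte lists were not called.

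**Figure D3:**
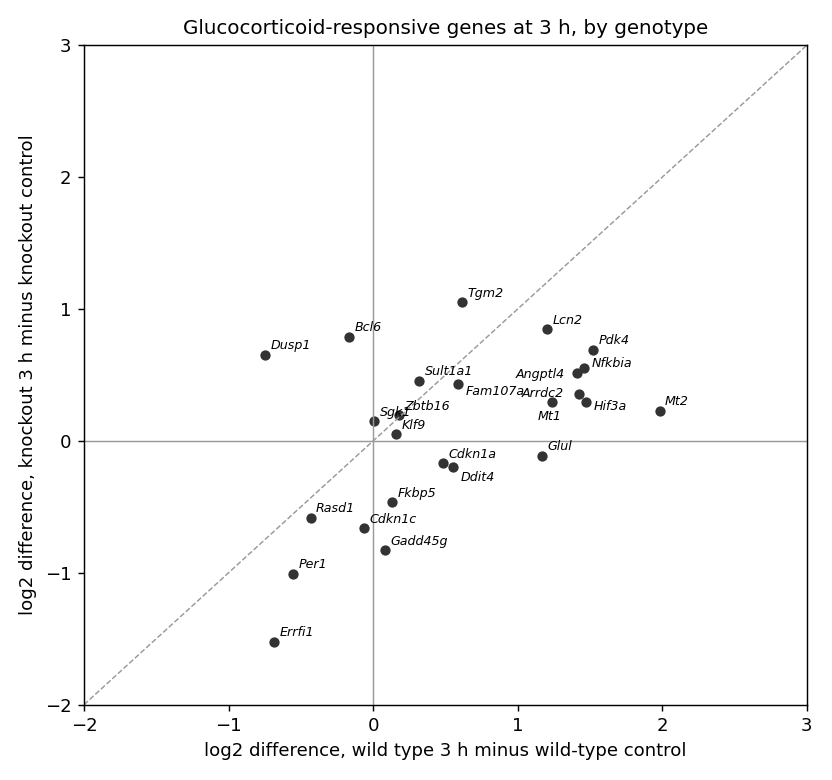
Log2 differences of the 25 glucocorticoid-responsive genes between 3 h and control in wild type (horizontal axis) and in knockout (vertical axis), with 1 point per gene and a dashed line of equal response. The medians were 0.48 in wild type and 0.23 in knockout.

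With pools as the unit, genotype was compared over all 3 treatments. Dnah9 was lower in knockout, at 5.94 ± 0.45 against 8.14 ± 0.20 (SD, n = 3 pools each, limma adjusted p = 0.0205), and was undetected in knockout controls. Corin, the protease that activates natriuretic peptides, was at least 1.37-fold lower (adjusted p = 0.0178), and Sec14l4, a lipid-transfer protein, at least 1.61-fold lower (adjusted p = 0.0482). Ugt8a, which lay outside the rule for named genes and was chosen after its values were seen, was lower and undetected in all 3 knockout pools, and the remaining calls were 2 unnamed probes, 1 higher and 1 lower. For each of these 6 features all 3 knockout pools lay beyond all 3 wild-type pools, which chance gives for 10% of features. Of 25 glucocorticoid-responsive genes, 6 were lower adjusted over the list alone and 0 over all genes, with a median of -0.48 and -1.54 ± 0.26 for Cdkn1a, a fitted value with 2 of the 3 knockout pools below detection (camera adjusted p = 2.08e-05, and adjusted p = 0.505 with an estimated correlation). All 9 leukocyte markers had positive differences, 3 of them higher adjusted over the list alone, with 1.24 ± 0.27 for the class II gene H2-Aa (camera adjusted p = 6.48e-05, and adjusted p = 0.435 with an estimated correlation). All 5 red blood cell markers were positive, with a median of 0.64 and 1 higher adjusted over the list alone (camera adjusted p = 4.55e-04, and adjusted p = 0.435 with an estimated correlation). Of 6 lactotrope markers 2 were lower, and of 6 gonadotrope markers 1 and of 7 fibroblast markers 2 were higher, adjusted over the list alone, with -1.33 ± 0.20 for Gal, 1.22 ± 0.28 for Fshb and 0.75 ± 0.18 for Mgp (adjusted p = 0.435, 0.435 and 0.505 with an estimated correlation). The count of 6 was 1 without knockout 3 h replicate 1, 40 without knockout 3 h replicate 2, 10 without wild-type 1 h replicate 2, 11 without wild-type 3 h replicate 1, 11 without knockout control replicate 1 and 30 without either 1 h pool. None of Dnah9, Corin and Sec14l4 passed under every omission of 1 array.

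Averaged over the genotypes, the pools gave 0 features past the threshold in limma at 1 h, with 229 at an unadjusted p under 0.05, and 0 at 3 h, with 1285, where chance gives 588. The largest differences of the activation genes at 1 h were 3.79 ± 0.81 for Fos and 2.08 ± 0.34 for Npas4 (SE), a fitted value with the knockout control pool below detection. Of 20 immediate early transcription factors, 13 were higher at 1 h adjusted over the list alone, 19 had positive differences and the median was 0.99 (camera adjusted p = 6.12e-30, and adjusted p = 0.201 with an estimated correlation). Glucocorticoid-responsive genes had medians of 0.30 at 1 h and 0.31 at 3 h, with 2 higher at 1 h, and 4 higher and 1 lower at 3 h, adjusted over the list alone (camera adjusted p = 3.96e-09 and 0.00874, and adjusted p = 0.486 and 0.721 with an estimated correlation). Socs3 differed by 1.82 ± 0.22 at 3 h, Nr4a2 by -1.95 ± 0.32 and Tshb by -0.97 ± 0.26, none past the threshold. Leaving out a whole pool gave between 0 and 10 features at 1 h and between 0 and 18 at 3 h. At 3 h the count was 24 without knockout 3 h replicate 2 and 1 without wild-type 1 h replicate 2 or wild-type 3 h replicate 1.

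Among the hormone genes, Pomc, Gh and Prl lay near the upper end of the scanner's range, where levels have no order. Apart from Tshb in knockout at 3 h, Tshb, Fshb, Lhb and Cga passed in no comparison. Cga, at a mean of 15.21 in the wild-type and 15.43 in the knockout pools, lay close below Pomc, so its not passing says little as well. Fshb, the follitropin subunit, differed by 2.08 ± 0.64 between the control pools (SE, n = 2 arrays per group, adjusted p = 0.122), and Tshb by -0.80 ± 0.18 in wild type at 3 h (adjusted p = 0.147). Of 6 corticotrope and melanotrope markers, 1 passed over all genes in any comparison: Tbx19, the transcription factor that activates Pomc, rose by 0.98 ± 0.23 in knockout at 3 h (adjusted p = 0.0321). In that comparison 1243 of all 11766 features passed, so 1 of 6 markers does not stand out. Neither Tbx19 nor Tshb passed there under every omission of 1 array.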

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

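Of the tests here, those on the control and stressed pools, on single probes and on the array with few detected probes were chosen after the result was seen, as were the test of gland markers on replicate 1 alone and the tests on genes neighbouring Crhr1 and on its chromosome, while the test of gland markers on both arrays and the splits of the pools were set before their results.

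Each value in the next 2 sentences stands out because the stress responses of the genotypes differed in the interaction test of limma, with knockout minus wild type on the log2 scale, as fitted values that for Emb, Cyp26b1, Spink8, Csrp1, Lipf, Dmbt1, Lyz1, Eme1 and Kcnk10 rest on groups below detection. At 1 h this held for 6 features, among them Emb (4.76), Cyp26b1 (3.48), Spink8 (2.69) and Ttc27 (2.52). At 3 h it held for 20 features, among them Csrp1 (4.27), Lipf (4.22), Emb (4.21), Fos (4.18), Dmbt1 (3.88), Lyz1 (3.48), Mt3 (3.37), Ddit4l (2.32), Rasgrp1 (2.04), Cyp26b1 (1.85), Eme1 (-2.66), Kcnk10 (-2.20), 1700109H08Rik (-2.13) and Pcbp4 (-1.81).

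The different responses may come from the receptor, which the design names and which was not tested apart from the pools, or from the control pools, from a stressed pool or from single probes. A difference that belongs to 1 stressed pool was not tested, so values that argue against the control pools do not argue for the receptor. A difference between the control pools as the source is argued against for 6 of the 26 calls, made on 24 features since Emb and Cyp26b1 were called at both times, whose control pools lay less than 1.5-fold apart, Lyz1, Dmbt1 and Rasgrp1 among them. Of the other 20 calls it is argued against as the whole source for 8 (Ttc27, Spink8, Mt3, Lipf, Pcbp4, 1700109H08Rik and 2 unnamed probes), whose stressed pools differed past the threshold in the direction of the call, while for the remaining 12, Emb, Cyp26b1, Fos and Csrp1 among them, it cannot be told apart from a response, since each group is 1 pool and 3 of the 12 (25%) had stressed pools less than 1.5-fold apart. Of these 3, Eme1 and Kcnk10 were below detection in both stressed pools. For Emb the stressed pools differed against the direction of the call, by -1.09 at 1 h and -1.64 at 3 h, against -5.85 in controls. Cyp26b1 at 3 h likewise had -1.22 against -3.07. Among the 8 calls above, the control pools of Ttc27 and Lipf differed in the direction of the call, by 0.78 and 0.61. That makes the fitted difference of responses smaller, not larger, though Lipf was undetected in both control pools. A signal of a single probe stays open as well, because 1 other probe of these genes was measured, for Rasgrp1, and it differed by 0.17 (adjusted p = 0.836) against 2.04 for the probe used. Among the named genes, Emb and Cyp26b1 at 1 h and Emb, Lipf, Dmbt1 and Mt3 at 3 h passed under every omission of 1 array.

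Lipf, Dmbt1 and Lyz1, genes of secretory epithelia, were high in the knockout 3 h pool, at 10.05, 9.53 and 8.36 on the log2 scale, where Lipf and Lyz1 were undetected in all other pools and Dmbt1 in wild type at 3 h and knockout at 1 h, and Bpifb1 lay 4.73 above wild type at 3 h. The array with few detected probes is argued against as the source, since 4 of the 4 genes passed the threshold against wild type at 3 h without it (adjusted p = 3.01e-04 for Lipf, Dmbt1 and Lyz1 and 0.0218 for Bpifb1). Tissue of an adjoining secretory gland in this pool, a possible explanation, cannot be told apart from a response: 0 of 32 other gland markers were detected on both arrays and at least 1.5-fold above the other pools (1.47% of other named genes, one-sided Fisher's exact p = 1), but that share predicts fewer than 1, and a probe had to reach 7.61 to be detected on replicate 2. On replicate 1 alone 2 of 32 passed, Wfdc18 at 7.07 and Amy1 0.87 above the slide's other arrays, against 3.79% of other named genes (one-sided Fisher's exact p = 0.344, odds ratio interval 0.196 to 6.70), while Pip was detected on replicate 2 alone, Scgb1a1 and Bpifa1 were undetected, and Wfdc2, which the other pools also express, was at 9.75. The 32 leave out gland markers whose values had already been seen. Of those, Ltf and Cldn10 were detected on both arrays, at 1.33 and 0.90 above the other pools. Tff2 and Lyz2 lay 1.33 and 1.55 above the other pools but were detected on replicate 1 alone. A difference that belongs to this 1 pool of mice, or to its place on the slides, was not tested and stays open beside a response to stress in knockout mice.

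The genes lower or higher in knockout at all 3 treatments numbered 6 in the comparison of pools. The 10 splits of the 6 pools into 3 and 3 are too few for a share under 0.05, with 6 genes for genotype, reached by 1 split, the real one, and 2 as the highest of the others. Strain sequence around the targeted gene, carried over from the cells used to make the knockout, could add such genes, and the 250 genes on either side of Crhr1 had an odds ratio of 1.26 (95% interval 0.397 to 3.05, one-sided Fisher's exact p = 0.376) for being among 281 genes that differed by at least 1.5-fold at an unadjusted p under 0.01. Sequence linked to Crhr1 and acting on its own neighbours is argued against for 2 of the 4 called features with a known chromosome, Corin on chromosome 5 and Ugt8a on chromosome 3, and 0 of the 4 lie in that window. Dnah9 and Sec14l4 lie elsewhere on chromosome 11, that of Crhr1, where the odds ratio was 1.09 (95% interval 0.692 to 1.64, one-sided Fisher's exact p = 0.376), so for these 2, and for the 2 unnamed probes without a position, strain sequence and loss of the receptor cannot be told apart, while strain sequence on other chromosomes was not tested.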

How the results depend on the processing

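The treatment of the 2 parts of the array apart and the comparisons of knockout with wild type at 1 h and 3 h were chosen after the data were seen, as was the comparison of values between the slides, and the other tests here were planned.

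The counts reported for the array comparisons, with limma, were 8 for wild type at 1 h, 27 for wild type at 3 h, 27 for knockout at 1 h, 1243 for knockout at 3 h, 271 between the controls, 6 and 20 for the difference of responses at 1 h and 3 h, and 93 and 203 for knockout against wild type at 1 h and 3 h. With pools as the unit they were 6 for genotype, 0 for stress at 1 h (229 at an unadjusted p under 0.05) and 0 for stress at 3 h (1285 at an unadjusted p under 0.05), where chance gives 588. Counts within 1.5 times of these are left out below. The cause was not tested for any of the changes that follow, except where the number of arrays or of features tested is given.

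With median centring in place of quantile normalization, the counts were 17 (14 higher and 3 lower, against 5 and 3) for wild type at 1 h, 70 (37 and 33, against 10 and 17) for wild type at 3 h, 494 between the controls, 11 (5 and 6, against 5 and 1) and 75 for the differences of responses, 320 for knockout against wild type at 1 h, and 20 for genotype and 5 for stress at 3 h with pools. Knockout against wild type at 3 h had 107 higher and 129 lower, against 64 and 139. The median of all features for the difference of responses at 3 h was -0.11, and 0.01 with this centring. The median of ribosomal protein genes between the controls was -0.01, and 0.22 with this centring, the only 1 of 252 list medians to change sign, among the settings run, for a list called by camera before or after the change.

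Without background correction the counts were 24 (19 higher and 5 lower) for wild type at 1 h, 73 (38 and 35) for wild type at 3 h, 114 (82 and 32, against 24 and 3) for knockout at 1 h, 35 (19 and 16) and 415 (204 and 211, against 14 and 6) for the differences of responses, 227 for knockout against wild type at 1 h, and 1 for stress at 3 h with pools. With the authors' values of the series matrix they were 10 (5 and 5) for wild type at 3 h, 12 for knockout at 1 h, 132 between the controls, 9 for the difference at 3 h and 38 for knockout against wild type at 1 h, and wild type at 1 h had 3 higher and 3 lower. With the 2 array parts apart they were 68 for the difference at 3 h, and 10 for genotype and 1 for stress at 3 h with pools.

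With no detection filter, which raised the features tested from 11766 to 34249, the counts were 11 for wild type at 3 h, 15 for knockout at 1 h, 690 for knockout at 3 h, 89 between the controls, 8 for the difference at 3 h, 35 and 98 for knockout against wild type at 1 h and 3 h, and 1 for genotype with pools. With detection required on all 12 arrays they were 13 and 91 for wild type at 1 h and 3 h, 197 for knockout at 1 h, 507 between the controls, 21 and 533 for the differences, 322 for knockout against wild type at 1 h, and 3, 2 and 1 for genotype, stress at 1 h and stress at 3 h with pools. With all probes counted, genotype with pools had 13. At least 2-fold left 582 for knockout at 3 h and 161 between the controls, and the adjusted p alone moved no count past 1.5 times.

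With the trend and robust options of eBayes the counts were 37 and 111 for wild type at 1 h and 3 h, 201 for knockout at 1 h, 597 between the controls, 85 and 541 for the differences, 370 and 423 for knockout against wild type at 1 h and 3 h, and 30 and 7 for genotype and stress at 3 h with pools. With array quality weights they were 20 and 89 for wild type, 112 and 111 for knockout at 1 h and 3 h, 875 between the controls, 36 and 7 for the differences, and 469 and 24 for knockout against wild type. Fitted on only the arrays of the groups compared, 4 arrays in a comparison and 8 in a difference of responses, they were 0 and 1 for wild type (958 and 1634 at an unadjusted p under 0.05), 3 and 0 for knockout (1810 and 2035), 12 between the controls, 7 for the difference at 3 h, and 0 and 3 for knockout against wild type (2125 and 890). The array-level fit in place of pools gave 432 for genotype, 30 for stress at 1 h and 539 for stress at 3 h.

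The labels pair no arrays beyond a shared replicate number, which is also the slide, so a fit with the slide as a block is the same fit and was not run apart. Deviations of same-numbered arrays from their group means correlated at -0.156 to 0.473 over 15 pairs of groups (median 0.155, 9 pairs over 0.1), so not every array deviated with those of its own number. Same-numbered arrays nonetheless share a slide by design, and the main fits leave the slide out. With the replicate number as a block the counts were 444 between the controls, 50 for the difference at 3 h and 219 for knockout against wild type at 1 h, and 482, 33 and 774 for genotype, stress at 1 h and stress at 3 h when the arrays replaced the pools in the same fit. The block ended 7 of 147 calls of named genes and 4 list calls in the array comparisons, each given with its comparison. It also added calls, which are not named: 76 among 1247 differences of named genes and 3 among 252 list results. These include the comparisons of pools, where arrays replaced the pools. Within each slide, differences over all features correlated between the 2 slides at 0.297 (wild type at 3 h) to 0.550 (knockout against wild type at 1 h), and between 12 and 17 of the 21 list medians had the same sign on both.

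Leaving out each of the 12 arrays in turn, with the lone array of a group assumed to vary like the other groups, gave 3 to 11 for wild type at 1 h, 2 to 90 for wild type at 3 h, 6 to 77 for knockout at 1 h, 26 to 3266 for knockout at 3 h, 2 to 773 between the controls, 2 to 12 and 4 to 1818 for the differences, 2 to 428 and 12 to 2597 for knockout against wild type, and 1 to 40, 0 to 0 and 0 to 24 for genotype, stress at 1 h and stress at 3 h with pools. The highest count came without replicate 1 of the knockout 3 h pool in all array comparisons but the difference at 1 h, where it came without knockout 1 h replicate 1. Leaving out each pool gave 6 to 30 for genotype, 0 to 10 for stress at 1 h and 0 to 18 for stress at 3 h.

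Of 147 differences of named genes past the threshold, 138 passed with median centring, 135 without background correction, 105 with the authors' values, 143 with the 2 array parts apart, 96 with no detection filter, 140 with the replicate block and 31 under every omission of 1 array, and 0 changed sign in these settings. Gene lists called with an estimated correlation numbered 0 in every comparison. Beside the number of arrays, signal over background is a limit: replicate 2 of the knockout 3 h pool had 6119 probes detected, and a gene undetected on both arrays of a group has only a bound for its fold there. The spread in the array comparisons is that of arrays of 1 pool, and the comparisons of pools have 1 pool per group. These settings therefore do not speak to the spread between mice.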

Other observations

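The comparisons of knockout with wild type at 1 h and 3 h, and the count of features called in all 3 treatments, were chosen after the data were seen, and the other tests here were planned.

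In knockout pituitaries at 3 h, where 1243 of all 11766 features passed, members of several lists passed although no list was called. The counts of members at 3 h were not tested against that share. Of 14 unfolded protein response genes, 3 rose over all genes and adjusted over the list alone: Atf4, the transcription factor of the integrated stress response, by 1.94 ± 0.33, the endoplasmic reticulum chaperone gene Hsp90b1 by 0.87 ± 0.20, and Chac1, which degrades glutathione, by 0.85 ± 0.17 (SE, n = 2 arrays per group). The camera test of this list gave no call (camera adjusted p = 0.0751). Of 13 clock genes, Bhlhe40 and 1 more rose, while Nr1d2 fell by 1.90 ± 0.29 (0.73 at a second Nr1d2 probe, adjusted p = 0.333) and Nfil3 by 0.89 ± 0.19. Of 11 heat shock genes, 2 fell, Hsph1 by 0.87 ± 0.17 and the small heat shock gene Cryab by 0.84 ± 0.16. Of 15 MAPK phosphatases and feedback genes, 2 rose and 3 fell, with -0.80 ± 0.17 for Rgs16 and -0.80 ± 0.20 for Dusp5. In knockout controls against wild-type controls, the same feedback list had 2 genes higher and 2 lower, with 1.19 ± 0.21 for Rgs4 and -1.18 ± 0.17 for Ier3.

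Averaged over the genotypes at 1 h, the lists of MAPK feedback genes (median 0.30, camera adjusted p = 1.22e-05, and adjusted p = 0.334 with an estimated correlation), of clock genes (median 0.31, camera adjusted p = 6.11e-04, and adjusted p = 0.486 with an estimated correlation) and of cAMP/CREB-responsive genes (median 0.13, camera adjusted p = 7.65e-04, and adjusted p = 0.334 with an estimated correlation) were called with the preset correlation. Red blood cell markers were called as lower (median -0.60, adjusted p = 0.334 with an estimated correlation), and folliculostellate markers were the other list called at 3 h (median 0.26, adjusted p = 0.659 with an estimated correlation). With pools as the unit, proliferation and interferon-induced genes were called as higher in knockout (medians 0.31 and 0.32, adjusted p = 0.505 and 0.435 with an estimated correlation) and cAMP/CREB-responsive genes as lower (median -0.26, adjusted p = 0.435 with an estimated correlation), with 0 members of these 3 lists called over the list alone. In the comparisons of knockout with wild type, 12 features passed the threshold in all 3 treatments, 11 lower and 1 higher in knockout. The 9 named ones were Dnah9, Emb, Cacna1h, Odr4, Corin, Gal, Ugt8a, Sec14l4 and Nktr, all lower and chosen after their values were seen.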
